A study of Agroathelia rolfsii with 6 samples.

How the data were processed

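Total RNA of 6 shake-flask cultures of Sclerotium rolfsii was hybridized to custom Agilent one-colour arrays with Cy3-labelled RNA, 1 array per culture. Per the labels, 3 cultures were grown in EPSmax13 and 3 in EPSmin17, as biological triplicates, and 500 ng of RNA entered each labelling. The sample titles and design text give 61 h of culture, while the labelling protocol states 37 h. The titles were followed. Probes were chosen for each unigene by a test hybridization of pooled RNA from both media, per the design text. No groups, pairs or batches other than the media are given in the labels.

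The deposited scanner files hold spot intensity on a linear scale. Per the file headers, the authors extracted them with Agilent Feature Extraction 9.5.3.1, which subtracted local background and corrected spatial trends to give the processed signal, with no scaling between arrays. The files also hold the raw mean and local background intensity, and flags for outlier spots, saturation and signal well above background. The median processed signal of the non-control probes was 299.3, 265.9 and 306.7 on EPSmax13 replicates 1 to 3 and 246.7, 206.8 and 235.3 on EPSmin17 replicates 1 to 3. Of the non-control spots on an array, at most 8 were flagged as outliers and at most 1 was saturated. Each array held 45220 spots, 1417 of them controls. The number of arrays limits the precision of every value, and no sequencing depth applies.

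The authors' deposited value table holds 1 intensity per unigene and array, with its scale unstated. Each of its columns was set against the scanner values of the same array. For 21860 of the 21881 rows that name no control (99.9%), the value was the geometric mean of the processed signals of one set of neighbouring probes on all 6 arrays, within a tolerance of 1e-05 on the natural log scale. The table is therefore linear, uncentred and not scaled between arrays. Its column medians were 300.8, 265.7 and 307.9 for EPSmax13 and 250.3, 207.5 and 235.4 for EPSmin17. The match tied 43661 probes of 60 bases to unigenes, 2 probes each for 21801 unigenes and 1 each for 59. The remaining 21 rows had no match, and 142 probes were tied to no unigene. No genome, annotation or description of the unigenes was used here. The 30 gene lists fixed beforehand matched 0 row names, so no gene list was tested, and neither were their alternative tests.

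Control spots and outlier-flagged spots were left out. Processed signals were quantile-normalized between arrays, as the design text describes, values below 5 were set to 5, and log2 was taken. Probes well above background on at least 3 of the 6 arrays were tested (31791 probes). A unigene was represented by its tested probe with the highest mean log2 signal over all arrays, which gave 16483 unigenes, 75.4% of those matched. Both probes were tested for 15170 unigenes. Both passed the threshold for 6753 of these, and went in opposite directions for 6. The probe pairs of one unigene mostly overlap in sequence, on the same strand for 16695 unigenes, so they are not independent measurements.

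EPSmax13 was compared with EPSmin17 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no covariate, at a Benjamini-Hochberg adjusted p under 0.05. The second result added a fold of at least 2. The design, the tests, the rule for named unigenes and the first set of alternatives were fixed before the data were examined. With no annotation, the rule names the 2 unigenes with the largest rise and the 2 with the largest fall, past the threshold and with no overlap between groups. Ranks were limited to unigenes well above background on at least 1 array of each medium, a condition applied after the data were seen, which replaced 1 rise whose EPSmin17 arrays were not well above background. For such unigenes a bound was computed as the mean log2 of the brighter medium minus the mean over the dimmer medium's arrays of the higher of the lowest signal well above background and the probe's own signal.

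The same steps were tested on simulated data for EPSmax13 against EPSmin17, with the probe means and spreads of the real arrays over 16483 unigenes. Of 100 unigenes changed 2-fold, 50.0% were recovered, and of 100 changed 4-fold, 85.0%. Only these unigenes were changed in the simulation, while 7901 were called in the real data. The adjusted threshold was therefore stricter in the simulation, and these shares do not carry over to the real comparison. Of the calls, 6.25% were false. The median estimates were 1.03 and 1.98 on the log2 scale.

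Alternatives were 75th percentile scaling, normexp background correction (offset 50) on the raw intensities, the value table, other filters, a floor of 1, other summaries of probes, a replicate block, slide as a fixed or random block, the methods' t-test, trended robust variances, array weights and the removal of each array. No scaling, spike-in scaling and the merging of unigenes with overlapping probes were added after seeing the data. Overlaps of at least 40 bases at 95% identity between probes were found with blastn 2.17.0. The arrays lay on 3 slides, each scanned on its own: slide 1 held EPSmax13 replicate 3 and EPSmin17 replicate 3, slide 2 EPSmin17 replicate 2, and slide 3 EPSmax13 replicates 1 and 2 and EPSmin17 replicate 1. Slide and scan batches are the same.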

Results

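Transcript levels of the filamentous basidiomycete Sclerotium rolfsii (listed under its current name, Agroathelia rolfsii) were measured in 2 liquid media that differ in whether they induce the fungus to secrete scleroglucan, a branched beta-glucan. EPSmax13, the inducing medium, supplied glucose at 40 g per litre, with sodium nitrate at 3.0 g per litre as nitrogen source. EPSmin17, the non-inducing medium, supplied fructose at 40 g per litre, with ammonium chloride at 1.9 g per litre. Carbon source and nitrogen source therefore changed together, and the comparison does not separate them from each other or from polysaccharide production. Cultures were grown for 61 h at 28 °C in 50 ml of medium at pH 4.5, with 3 biological replicates per medium and 1 one-colour (Cy3) custom Agilent array per replicate. Between 67.3% and 76.3% of the non-control probes on an array were well above background. The files carry unigene names (assembled transcript contigs) but pair none with a gene description, so levels are reported by unigene name and no gene function is given for them.

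The question was which transcripts differ between the inducing and the non-inducing medium. Transcripts differed over much of the detected transcriptome. Of 16483 unigenes tested, 4037 were higher and 3864 were lower in EPSmax13, 47.9% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 per medium). Most of these differences were small: 4752 of the 7901 changed unigenes differed by less than 2-fold, and the median fold (a ratio of geometric means, as are all folds here) was 1.90 among those that were higher and 1.78 among those that were lower. At 2-fold or more, the limit set by the study, 3149 unigenes changed, 1791 higher and 1358 lower in EPSmax13.

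**Figure D1:**
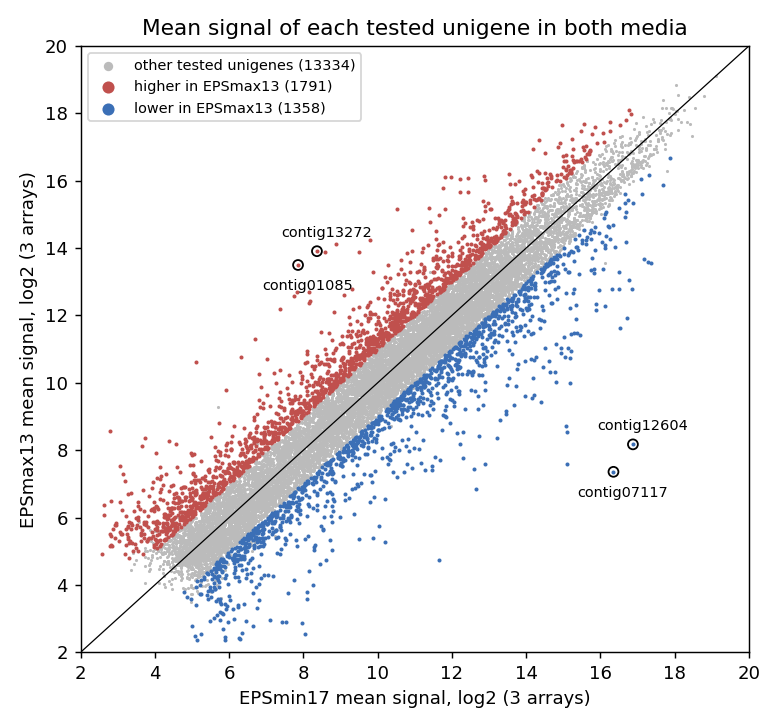
Mean quantile-normalized log2 signal of each of the 16483 tested unigenes in EPSmin17 (horizontal axis) and EPSmax13 (vertical axis), each a mean of 3 arrays; red points are the 1791 unigenes at least 2-fold higher and blue points the 1358 at least 2-fold lower in EPSmax13, the line marks equal signal, and circles mark the 4 unigenes named in the text. Both sets of points run along the whole signal range, and the circled falls lie farther from the line than the circled rises.

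After quantile normalization, differences of 8-fold or more were more numerous among the unigenes that were lower in EPSmax13. Counting only unigenes well above background on at least 1 array in each medium, 267 rose and 266 fell by at least 4-fold. At 8-fold or more 53 rose and 105 fell, at 16-fold or more 19 rose and 40 fell, and at 32-fold or more 5 rose and 10 fell. The 8-fold counts were 31 and 99 without EPSmax13 replicate 1 and 77 and 88 with unscaled signals, and the order turned to 93 and 79 with spike-in scaling. The groups did not overlap, with all 3 arrays of one medium above all 3 of the other, for 59.3% of the tested unigenes, where chance gives 10%. This held for 7848 of the 7901 changed unigenes. The median SD between replicates was 0.23 on the log2 scale in EPSmax13 and 0.18 in EPSmin17.

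The 2 largest falls measured in both media were those of contig07117 and contig12604. The log2 signal of contig07117 was 7.36 ± 1.64 (SD, n = 3) in EPSmax13 and 16.35 ± 1.10 (SD, n = 3) in EPSmin17. The log2 difference was -8.99 (SE 0.84, limma adjusted p = 0.000495), a geometric mean signal 510-fold lower in EPSmax13. It is read by the probe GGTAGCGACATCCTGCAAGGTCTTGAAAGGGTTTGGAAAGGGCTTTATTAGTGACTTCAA, and its other probe gave a log2 difference of -9.22. The log2 signal of contig12604 was 8.17 ± 2.21 (SD, n = 3) in EPSmax13 and 16.87 ± 0.19 (SD, n = 3) in EPSmin17, a log2 difference of -8.70 (SE 0.95, limma adjusted p = 0.000755) or a 417-fold lower geometric mean signal. Its probe is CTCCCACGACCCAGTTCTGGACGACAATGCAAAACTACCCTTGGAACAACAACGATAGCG. The geometric mean signals were 83557 in EPSmin17 against 164 in EPSmax13 for contig07117, and 120156 against 288 for contig12604. Within slides, contig07117 differed by -10.17 on slide 1 and -9.50 on slide 3 (log2), and contig12604 by -10.23 and -7.78. With slide as a block the log2 difference was -9.79 for contig07117, an 884-fold lower signal, and -8.83 for contig12604. EPSmin17 replicate 2 was alone on its slide and adds nothing to these values, which rest on slides 1 and 3. The size of both falls rested on single arrays. Without EPSmax13 replicate 1 they were 971-fold and 1006-fold, and without EPSmax13 replicate 3 they were 333-fold and 256-fold. The fall of contig07117 also varied with the EPSmin17 arrays: it was 346-fold without EPSmin17 replicate 1 and 739-fold without EPSmin17 replicate 2. With normexp background correction the falls were 314-fold and 328-fold, so the order of the 2 depends on the processing.

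The 2 largest rises measured in both media were smaller than these falls. The log2 signal of contig01085 was 13.50 ± 2.03 (SD, n = 3) in EPSmax13 and 7.86 ± 0.23 (SD, n = 3) in EPSmin17, a difference of 5.64 (SE 0.87, limma adjusted p = 0.00248) or 49.9-fold. Its probe is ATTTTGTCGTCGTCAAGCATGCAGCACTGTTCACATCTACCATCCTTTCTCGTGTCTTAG. The log2 signal of contig13272 was 13.91 ± 2.00 (SD, n = 3) in EPSmax13 and 8.36 ± 0.17 (SD, n = 3) in EPSmin17, a difference of 5.54 (SE 0.86, limma adjusted p = 0.00248) or 46.6-fold. Its probe is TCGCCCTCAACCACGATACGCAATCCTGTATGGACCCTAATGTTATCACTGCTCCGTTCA. The second probes of these unigenes gave log2 differences of 5.75 and 5.51. Both unigenes were brightest on EPSmax13 replicate 1, at 15.82 and 16.20, and lay at 12.62 and 13.00 on replicate 2 and at 12.05 and 12.52 on replicate 3. Without replicate 1 the rises were 22.3-fold and 21.0-fold, and without replicate 3 they were 82.3-fold and 75.5-fold. Within slides the log2 differences of contig01085 were 4.31 on slide 1 and 6.10 on slide 3, and those of contig13272 were 4.24 and 6.05. With slide as a block, which leaves EPSmin17 replicate 2 without weight, they were 5.33 and 5.27.

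**Figure D2:**
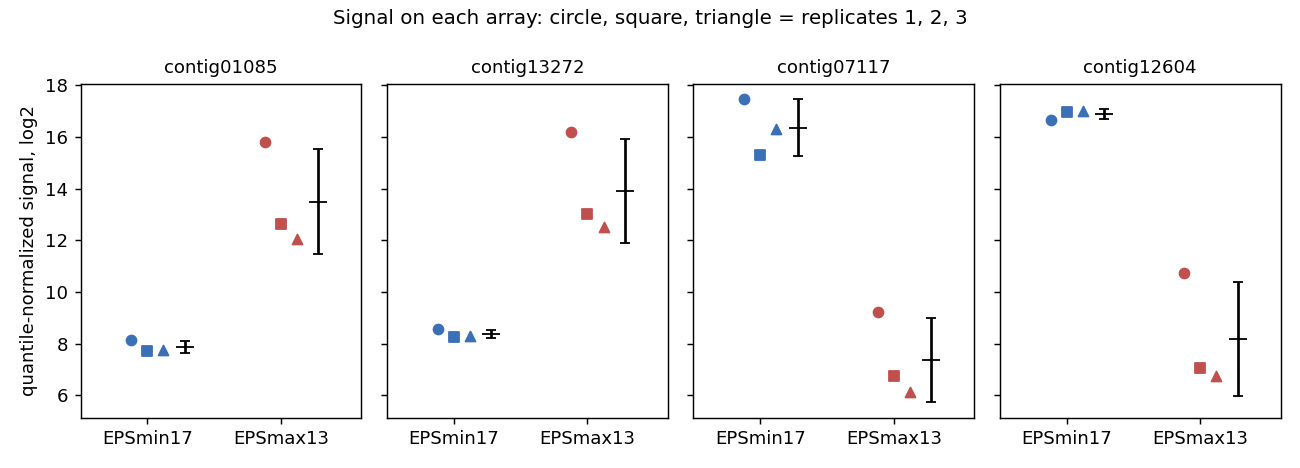
Quantile-normalized log2 signal of the 4 named unigenes on each array; circles, squares and triangles are replicates 1, 2 and 3, and the dash with its bar is the mean ± SD of the 3 arrays of a medium. All 3 EPSmax13 arrays lie above all 3 EPSmin17 arrays for contig01085 and contig13272 and below them for contig07117 and contig12604, and in each of the 4 the EPSmax13 replicate 1 array has the highest signal of its medium.

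Some transcripts were detected in one medium only. All 3 EPSmax13 arrays and no EPSmin17 array were well above background for 89 unigenes, and the reverse held for 122. Of these, 87 rose and 110 fell in EPSmax13 (limma, adjusted p under 0.05). They were picked by detection on the same arrays, which favours these directions, so the test adds no independent support. Because one side was not well above background, each such difference is a lower bound, set by the lowest signal that was well above background on each array. The median bound was at least 2.34-fold higher for the 87 and at least 2.10-fold lower for the 110, and the largest bounds were at least 16.6-fold higher and at least 14.6-fold lower. In both media 14566 unigenes were well above background on every array, and 3332 were so on no array.

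Unigenes changed by 2-fold or more occurred at every signal level: with the tested unigenes divided by mean signal into 5 groups of equal size, 12.8% were higher and 8.89% lower in the dimmest group, and 10.6% were higher and 7.52% lower in the brightest.

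**Figure D3:**
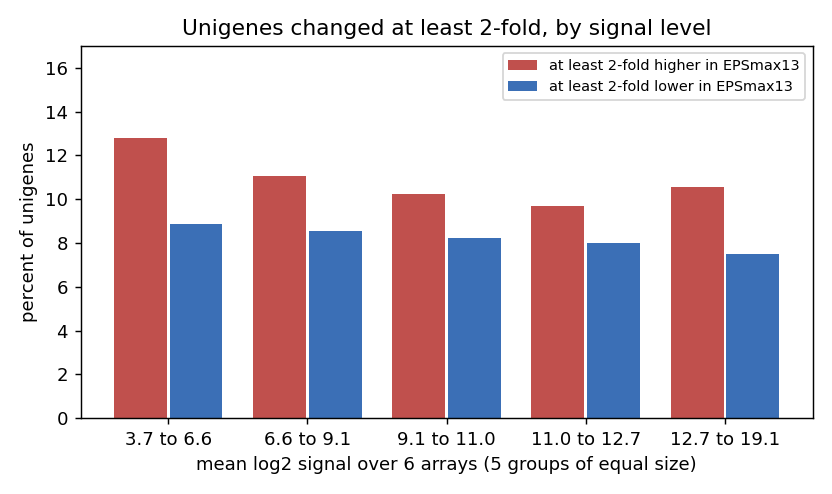
Percent of tested unigenes at least 2-fold higher (red) or lower (blue) in EPSmax13, in 5 groups of equal size by mean log2 signal over the 6 arrays (horizontal axis, log2 range of each group). Red bars are taller than blue bars in every group, with 12.8% higher and 8.89% lower in the dimmest and 10.6% and 7.52% in the brightest.

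A few array rows carry a gene-like name in place of a contig number. They were picked for their names after the values were seen, and the files hold no description of them. The row cbh-1 (a symbol commonly used in fungi for a cellobiohydrolase, a cellulose-degrading enzyme) was well above background on all 6 arrays, at a log2 signal of 5.43 ± 0.43 (SD, n = 3) in EPSmax13 and 5.61 ± 0.27 (SD, n = 3) in EPSmin17, and did not pass the test (limma adjusted p = 0.566). This is a dim row, within the dimmest of the 5 signal groups (up to 6.58). Its other probe was well above background on only 2 of 3 EPSmin17 arrays. The row named oxdc, an abbreviation often used for oxalate decarboxylase, had a log2 signal of 7.89 ± 0.25 (SD, n = 3) in EPSmax13 and 7.50 ± 0.11 (SD, n = 3) in EPSmin17. Its log2 difference of 0.39 (SE 0.17) did not pass the test (limma adjusted p = 0.0939), and its dimmer probe lay at 6.42 ± 0.20 and 6.54 ± 0.46. The rows ATPase, cellobiose, fdhS, gpdS and oxox were well above background on too few arrays to be tested. ATPase was so on 2 EPSmin17 arrays and fdhS on 1, and the remaining rows on none.

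The split of higher against lower calls depended on how arrays were scaled to each other. With signals left unscaled, a choice made after seeing the data, 5155 unigenes were higher and 1641 lower in EPSmax13, 75.9% higher against 51.1% after quantile normalization, and the median log2 difference of all tested unigenes was 0.26, against -0.0093 after quantile normalization. At 2-fold or more the unscaled split was 2924 higher and 792 lower, 78.7% higher against 56.9%. Signals were also scaled to the median of the spike-in spots well above background on each array, a set of spots that may differ between arrays. With this scaling 1961 unigenes passed the threshold, all by at least 2-fold, 1617 higher and 344 lower, with a median log2 difference of 0.40. All unigenes of an array share its spike-in error, which the test treats as independent between unigenes. Its p-values are therefore too small (contig07117, limma adjusted p = 2.12e-51), and these counts are not a working test. All directions above are therefore relative to the distribution of all unigenes. The arrays lay on 3 slides: with slide as a block, 5693 unigenes changed, 2946 of them by at least 2-fold. EPSmin17 replicate 2 was alone on its slide, so this fit compared the media on slides 1 and 3 only. The lower count thus also reflects fewer usable arrays. In a check chosen after seeing the data, unigenes were called at 2-fold on the arrays of the other slides only (limma). Of 2843 called without slide 1, 2823 had the same sign on slide 1, 2029 of them at 2-fold or more. Of 3154 called without slide 3, where EPSmax13 had 1 array left and its spread was taken from EPSmin17, 3054 had the same sign on slide 3, 2283 of them at 2-fold or more.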

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

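The 142 probes tied to no unigene were outside the comparison, and most of them gave a signal: 138 were well above background on at least 3 arrays, and 127 were so on all 6. Tested as single probes among all tested probes, 83 of them changed between media (limma, adjusted p under 0.05), 45 higher and 38 lower in EPSmax13, and 44 changed by at least 2-fold. They have no unigene name here and add to none of the counts in the report.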

How the results depend on the processing

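No scaling, spike-in scaling and the merging of overlapping unigenes were chosen after seeing the data; the other alternatives were planned. Of 24 alternatives, 22 gave a count of changed unigenes within 1.5 times the 7901 reported, and 22 did so for the 3149 changed at 2-fold. Testing each probe on its own gave 15464 and 6164, which count probes in place of unigenes. Spike-in scaling gave 1961 changed unigenes, and all 1961 differed by at least 2-fold. The spike-in medians varied between EPSmax13 arrays with an SD of 0.84 on the log2 scale, which this scaling adds to every unigene. The test treats this shared error as independent between unigenes, so its p-values and counts cannot be relied on. The medians were taken over the spike-in spots well above background on each array, so part of this spread may come from a differing set of spots. Without scaling, 6796 changed, 3716 at 2-fold, of which 2924 were higher and 792 lower. Leaving out single arrays gave 5704 to 7458 changed unigenes and 2843 to 3303 at 2-fold. Merging unigenes with overlapping probes left 7610 of 16027, and normexp gave 7824, of which 2102 at 2-fold. The methods' t-test gave 2994 unigenes at its own limits (2-fold, unadjusted) and 2577 at 2-fold after Benjamini-Hochberg. A floor of 1 moved neither count. The random slide block (correlation 0.021) gave 7953.

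The replicate block gave 8402 changed unigenes, 3127 at 2-fold. Deviations of same-numbered arrays from their group means correlated at 0.085, 0.182 and 0.287 across unigenes, so not every pair passed 0.1 and the numbers were not taken to pair the cultures. Each EPSmax13 array correlated best with its own number, as did each EPSmin17 array, but replicates 1 and 3 also shared a slide. EPSmax13 replicate 2 and EPSmin17 replicate 1 shared a slide too, at -0.00037, while the replicate 2 arrays (0.182) lay on different slides. Pairing by number therefore stays open. The 4 named unigenes kept their direction and passed the threshold under all 24 alternatives, though the pass with spike-in scaling carries no weight. Their log2 differences ranged from 4.48 to 6.36 for contig01085, from 4.40 to 6.24 for contig13272, from -9.92 to -8.29 for contig07117 and from -9.98 to -8.00 for contig12604. The cbh-1 row, which passed no test, turned to 0.025 without scaling and to 0.17 with spike-in scaling. The oxdc row passed with array weights (adjusted p = 0.0322) and without scaling (adjusted p = 0.024), over a range of 0.024 to 0.676; the cause was not tested. In 10 splits of the 6 arrays into 3 and 3, the real one gave 7901 and 3149 and the highest of the others 0 and 0. Each other split mixes both media in both groups, so the difference between media widens the spread and holds calls down. The counts of 0 are thus no measure of chance. With 10 splits, 1 of them the real one, the share cannot go under 0.05. Signal over background limits the dimmest unigenes: 5377 had no probe to test.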

Other observations

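Beside the numbered contigs, the arrays carry rows with other names, which were examined only after the data were seen. Of 35 tested rows named as lettered clones, 9 were at least 2-fold higher and 3 at least 2-fold lower in EPSmax13, 34.3% against 19.1% of the contigs (Fisher's exact test, two-sided, p = 0.0301, Benjamini-Hochberg adjusted p = 0.0602 over 2 classes). This difference did not pass the adjustment. Of 27 tested rows named by a bare number, 10 were higher and 6 lower (limma, adjusted p under 0.05), and 3 and 2 were so by at least 2-fold, 18.5% of the class. Of 12 rows with other names 5 were tested, among them cbh-1 and oxdc, and 3 changed. The row whose name is "G2," was lower in EPSmax13, at a log2 signal of 13.60 ± 0.27 (SD, n = 3) against 17.29 ± 0.14 (SD, n = 3), a difference of -3.68 (limma adjusted p = 6.08e-05), or 12.9-fold. The row named Gene was lower by 3.67-fold (log2 difference -1.88, limma adjusted p = 0.00393), and a row named by its own probe number was 1.97-fold higher (log2 difference 0.98, limma adjusted p = 0.00473). The last 2 did not pass with spike-in scaling (adjusted p = 0.0553 and 0.0783, the highest of their alternatives; the lowest were 0.00145 and 0.00114). The row B1.seq was the brightest tested row on every array, so quantile normalization gave it the same value, 19.11, on all 6 and no difference between media can be read from it.

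Below, the test of the array scale was fixed before its result was seen; the tests of the slide, of the larger response, of the opposite strand and of the spike-ins were chosen only after these or closely related values had been seen. EPSmax13 replicate 1 stood apart from its group most often: 718 unigenes lay outside both other replicates and at least 2-fold from their mean, 386 above and 332 below, against 166 to 532 for the other 5 arrays. Whether that array had a wider signal scale was not settled. The direction of these departures did not follow the signal level (r = -0.044 across unigenes, which are not independent). But the departures were measured after quantile normalization, which gives every array the same distribution and so removes a wider scale beforehand. EPSmin17 replicate 1, on the same slide, moved by a median of 0.058 of the departure (quartiles -0.195 and 0.296). EPSmax13 replicate 2 lay on that slide too, and the departures were picked to lie outside that replicate. Unigenes moved by the slide were thus selected against, so this value cannot decide on a slide effect. A candidate explanation is a larger response to the medium in that culture: of 400 of these unigenes that also changed without that array, 68.3% departed in the direction of the difference between media, 75.1% of those higher and 60.7% of those lower in EPSmax13. It would not account for all departures, since contig07117 and contig12604 went the other way, and the labels give nothing else by which cultures of one medium differ.

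Probes of 143 pairs of unigenes overlap on opposite strands. In the 91 pairs with both probes tested the dimmer lay a median of 5.77 log2 units below the brighter (quartiles 4.19 and 7.07), while their log2 fold changes correlated across pairs at r = 0.81. Some pairs share a probe, among them those with the largest falls, so the pairs are not independent, as r and the intervals below take them to be. The gap also depends on how well each probe binds, so it does not bear on the source of the dim signal. Separately regulated RNA from the other strand stays open. Of 32 pairs with both probes changed, 2 (6.25%, exact 95% interval 0.766% to 20.8%) went in opposite directions. Of all 91 pairs, 21 had differences of opposite sign (23.1%, exact 95% interval 14.9% to 33.1%). In 10 of these neither probe passed the threshold, and in only 1 were both differences at least 2-fold. One fixed share of label on the opposite strand would give both probes the same change. The difference between their changes, tested itself (limma, adjusted p under 0.05), passed in 6 of the 91 pairs (6.59%, exact 95% interval 2.46% to 13.8%). All 6 had opposite signs, with the smaller change on the dimmer probe. At an unadjusted limma p under 0.05 the difference passed in 17 of the 91, so pairs beyond the 6 may depart as well. A fixed share may hold for the rest and stays open. RNA from the other strand that moves with its partner may also give this pattern, and the design names no biological difference that would separate these.

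Unscaled signals were higher in EPSmax13 by a median of 0.26 log2 units over the tested unigenes. Brighter labelling or scanning would raise the spike-in controls as well, and these differed by -0.14 log2 units (EPSmax13 minus EPSmin17), with an SD between arrays of one medium of 0.61. The median of each array covers only its spike-in spots well above background, so the spots behind it may differ between arrays and widen this spread. Each labelling took the same 500 ng of total RNA, so only a rise of transcripts relative to total RNA could show. The spike-in spread is wider than the shift, so array brightness and such a rise in EPSmax13 cannot be told apart here. The split of higher against lower calls stays tied to the scaling.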
